A study of Rattus norvegicus with 16 samples.

How the data were processed

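Gene expression was measured in the extensor digitorum longus (EDL), a fast-twitch muscle of the lower hind limb, of Brown Norway rats aged 6 months. The 16 arrays fell into 8 from control, innervated muscle and 8 from muscle denervated for 2 months, per the labels. Rats were numbered 1 to 8 in both groups, and the labels used here do not say whether a number marks the same animal. Each array was taken as 1 rat.

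Per the labels, labelled cDNA was hybridised to Clontech Atlas rat nylon membranes, imaged on a phosphorimager, quantified with Array Vision software and normalised by linear regression. The deposited values are a score on a logarithmic scale, as the values themselves show. The base of the logarithm, the background correction and the origin of the lowest values are not given in the sources used here. Differences are therefore given in log units and no fold changes are printed; a difference of 1 log unit would be a 2-fold change with base 2 and a 2.72-fold change with base e. On every array the lowest value was repeated on 22 to 206 probes and is called the array's floor. A value at the floor gives only an upper bound on the level.

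The table held 1185 probes. Of these, 9 carried reference genes whose values lay on another scale, and they were left out of the main tests after the data were examined. None of the 1176 remaining probes had a value of 0 or below, so the filter set beforehand, a value above 0 on at least 8 arrays, removed none. The platform table paired 1106 of the tested probes with 1 gene, 2 with several genes and 68 with none, and all 1106 gene IDs were found in a RefSeq gene table of assembly GRCr8, used for names only. For the 10 genes with several probes, the probe with the highest mean over all arrays entered the gene lists. Probes on such membranes can also bind transcripts of close relatives of the named gene. Median values of the control arrays of rats 1 to 8 were 8.10, 8.12, 8.12, 8.41, 8.39, 6.98, 8.51 and 8.22, and those of the denervated arrays were 8.18, 8.20, 8.07, 7.97, 8.54, 8.48, 8.60 and 8.49.

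Values were used as deposited, without further scaling. Denervated and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided), and Benjamini-Hochberg adjusted p-values under 0.05 over the tested probes counted as changes. All adjusted p-values for probes are limma's unless an exact permutation test is named. Of 22 gene lists fixed before the data were examined, the 17 with at least 3 measured members were tested with limma's camera, which compares a list with all other probes, at its preset correlation between genes of 0.01, with adjustment over the lists. The same test with the correlation estimated from the data is given beside it. Camera compares the mean of the members' test statistics with that of the other probes. A list median printed beside its p-value is therefore descriptive and was not itself tested. The ribosomal protein list was defined by a pattern of gene symbols, which also took in the kinase Rps6kb1. Single values were compared by exact two-sided permutation over the 12870 ways to choose 8 of 16 arrays, whose smallest possible p is 0.000155. The number of arrays limits the precision.

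Named genes followed a rule fixed beforehand, comprising up to 12 of the largest rises and 12 of the largest falls among changed probes with 1 gene, the 3 members of each tested list with the lowest adjusted p, and a set of textbook denervation and reference genes where measured (among them Chrna1, Chrnd, Chrng, Chrne, Myog, Myod1, Musk, Ncam1, Gapdh and Actb). Genes named outside the rule are said to be so. Values for the acetylcholine receptor genes and for 1 other item of the rule are not reported here, and Gapdh and Actb were among the 9 reference probes.

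The procedure was tested on simulated data for the comparison of 8 with 8 arrays, with 200 of 1176 probes changed. limma recovered 26% of changes of 1 log unit and 88% of changes of 2 log units, and 8.06% of its 124 calls were false. A list of 18 genes raised by 1 log unit was called at an adjusted p of 7.55e-05, and 1 of 100 unchanged lists passed at an unadjusted p. The simulated noise was independent between probes, without correlated genes, sets of rats, a low array or floors. These rates therefore may not hold for the real arrays. Alternatives fixed before the data were examined were centring of each array, quantile normalisation, no filter, the brighter part of the probes, rat number as a block, robust variance, array weights, an exact permutation test per probe, an estimated correlation and leaving out each array in turn. Those added after the data were seen were inclusion of the reference probes, a filter on floor values, a common floor, the split between rats 1 to 4 and rats 5 to 8 as a block or as separate fits, both scalings with blocks, and the ribosomal list without the kinase. Figures were drawn with matplotlib 3.10.9.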

Results

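The transcripts of rat EDL muscle were measured on 8 arrays from innervated control muscle and 8 arrays from muscle denervated for 2 months, over 1176 probes. Mean values over probes lay between 8.19 and 8.31 log units on 15 arrays, while the array of control rat 6 had a mean of 6.63. The median standard deviation of a probe between rats was 0.987 log units in control and 0.772 in denervated muscle. No 2 arrays were copies, as the highest share of identical values in any of 120 pairs was 0.085%.

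**Figure D1:**
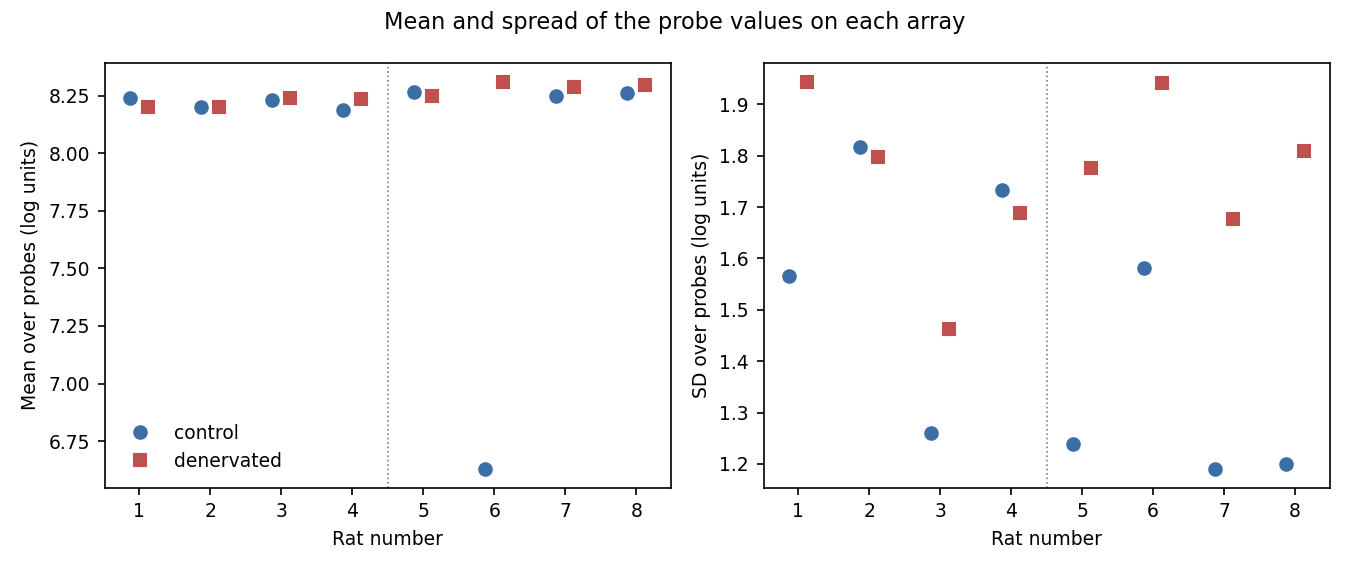
Mean (left) and standard deviation (right) over 1176 probes on each array in log units, by rat number, with circles for control and squares for denervated muscle and a dotted line between rats 4 and 5. The array of control rat 6 lies at a mean of 6.63, and the other 15 arrays lie between 8.19 and 8.31.

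The comparison of denervated with control muscle asked which transcripts differed after 2 months without a nerve supply. The largest difference in means was that of Tnnt2, the cardiac and embryonic form of the thin-filament protein troponin T. Its values rose from 6.12 ± 1.27 to 11.46 ± 0.90 log units (SD, n = 8 per group). Control values were at the floor on 4 of 8 arrays for Tnnt2 and on 6 of 8 for Cox8a, which differed by 4.84. Control levels there are upper bounds, so the order of these rises is not settled. The low array of control rat 6, at its floor for both genes, enlarged both differences. Without it Tnnt2 differed by 4.93. After centring the differences were 5.13 for Tnnt2 and 4.63 for Cox8a. Myh3, the embryonic myosin heavy chain, rose from 5.60 ± 1.04 to 9.28 ± 1.36, and Runx1, a transcription factor known to be induced by denervation, rose from 6.71 ± 1.04 to 10.26 ± 0.41. Ncam1, a cell adhesion molecule, rose by 1.96 and Myog, the myogenic transcription factor myogenin, by 1.85. Pfkfb1, an enzyme that sets the level of an activator of glycolysis, fell by 2.13, and Mylk2, the myosin light chain kinase of skeletal muscle, fell by 1.87.

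In all, 74 of the 1176 probes changed, 64 higher and 10 lower in denervated muscle, and 211 passed at an unadjusted p under 0.05. All 74 differed by at least 1 log unit. The lack of smaller calls reflects the threshold at least in part, since limma recovered only 26% of simulated changes of 1 log unit. Among all 1176 probes the groups did not overlap in 15, all of them within the 74, where random grouping of the arrays gives 0.0155% of probes. The median difference over all probes was 0.22, so each rise is smaller and each fall larger by that amount relative to the array as a whole. Centring each array moved this median to 0.01 and the counts to 35 higher and 15 lower. Quantile normalisation moved it to -0.01 and the counts to 35 higher and 27 lower. The share of calls that were higher thereby went from 86.5% to 70.0% and 56.5%. Without the array of control rat 6 the median difference was 0.03 and the counts were 48 higher and 14 lower. Leaving out other single arrays gave 43 to 98 changed probes. The count was 43 without denervated rat 1, 45 without control rat 7, 46 without denervated rat 6, 48 without control rat 8 and 49 without control rat 5.

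**Figure D2:**
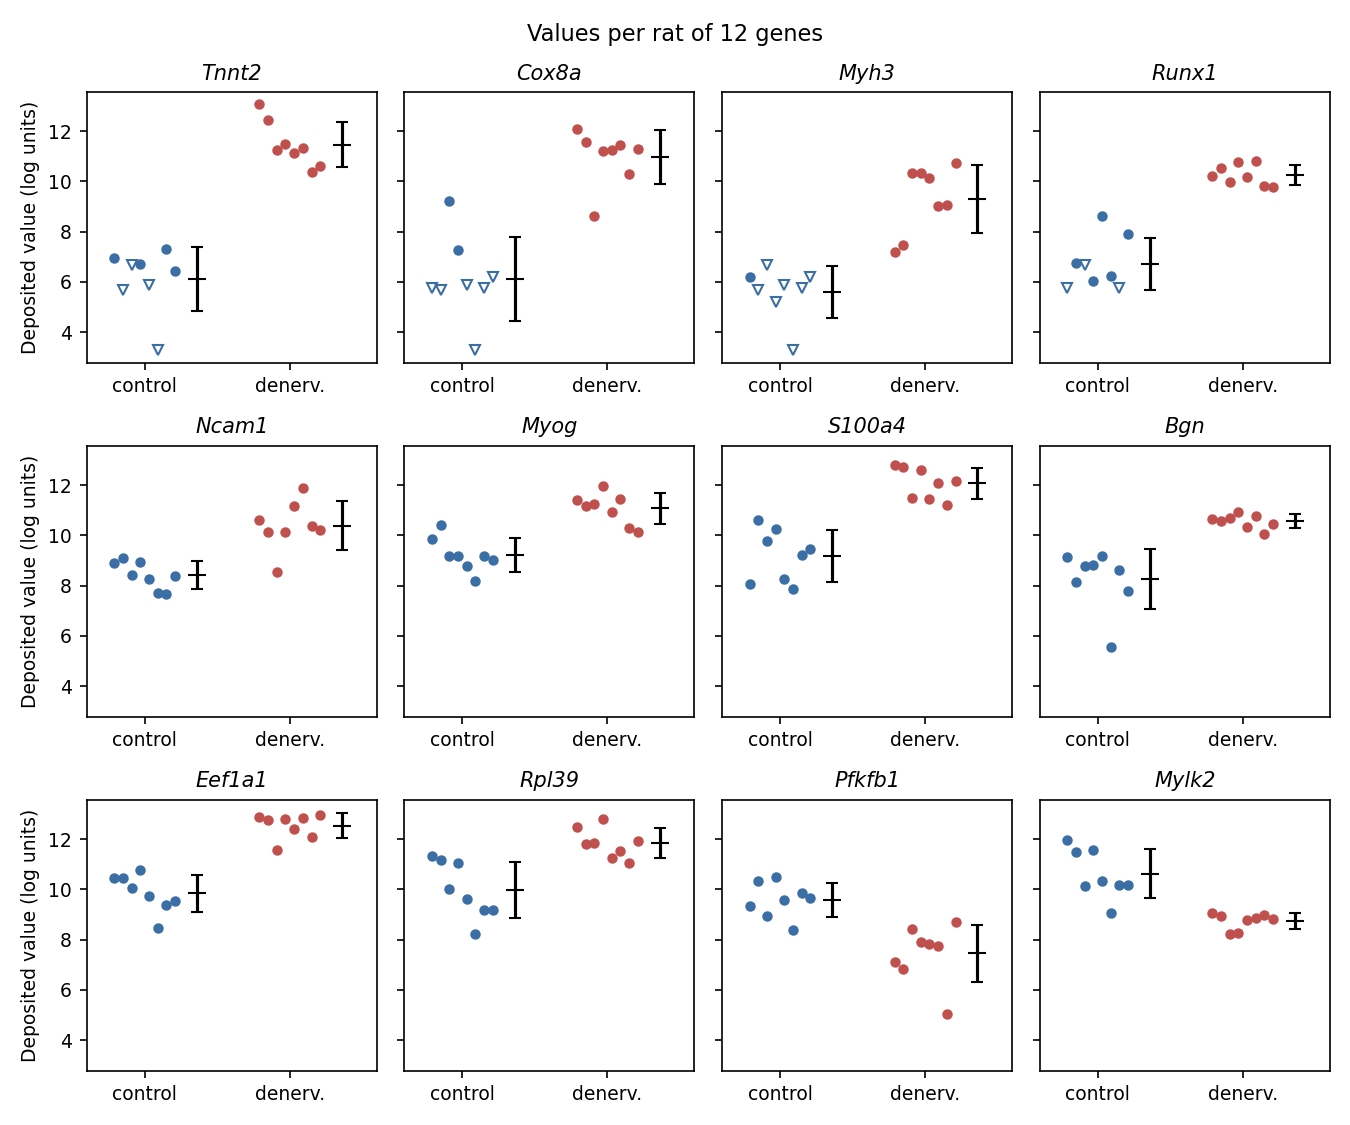
Deposited values in log units of 12 genes on each array, in control (blue) and denervated (red) muscle, with filled circles for measured values, open triangles for values at the array's floor, and black bars for mean and standard deviation (n = 8). Tnnt2, Myh3, Runx1, S100a4, Bgn and Eef1a1 were higher in every denervated array than in any control array, and Mylk2 was lower in every denervated array.

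Among slow and developmental contractile genes, 3 of 6 measured members rose (4 adjusted over the list alone) and none fell. They were Tnnt2 by 5.34 (SE 0.44, adjusted p = 1.44e-13), Myh3 by 3.68 (SE 0.55, adjusted p = 2.15e-06) and Casq2, the calcium-binding calsequestrin of cardiac and slow muscle, by 1.77 (adjusted p = 0.00126). The list lay higher than other probes, with a median 1.18 above that of all probes (adjusted p = 1.09e-05, and adjusted p = 0.0816 with an estimated correlation). Control values were at the floor on 4 of 8 arrays for Tnnt2 and 7 of 8 for Myh3, so their control levels are upper bounds there.

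Of the 6 measured neuromuscular junction and denervation-response genes, 2 rose (2 adjusted over the list alone), Runx1 by 3.54 (SE 0.41, adjusted p = 6.06e-09) and Ncam1 (adjusted p = 3.43e-04). Runx1 was at the floor on 3 of 8 control arrays. Ncam1 differed by 1.01 in rats 1 to 4 and by 2.92 in rats 5 to 8, the set that holds the low array of control rat 6. Musk, the receptor kinase that organises the synapse, differed by 0.73 (adjusted p = 0.310), and by 0.45 without control rat 6. The list was higher by a median of 0.43 relative to all probes (adjusted p = 0.00309, and adjusted p = 0.177 with an estimated correlation).

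Of 5 myogenic regulators, 3 rose (3 adjusted over the list alone), namely Myog (adjusted p = 3.79e-04), Myod1 by 1.33 (adjusted p = 0.0450) and Myf6 by 1.29 (adjusted p = 0.0203). The list was higher by a median of 1.08 relative to all probes (adjusted p = 0.00867, and adjusted p = 0.336 with an estimated correlation). After quantile normalisation the list (adjusted p = 0.0937), Myod1 (adjusted p = 0.182) and Myf6 (adjusted p = 0.0594) no longer passed, and Myog did (adjusted p = 1.57e-04). After centring Myod1 did not pass either (adjusted p = 0.157).

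Ribosomal proteins formed the list with the lowest p at the preset correlation, and slow and developmental contractile genes that with the lowest p at an estimated correlation. Of 18 members, 10 rose (13 adjusted over the list alone) and all 18 differences were positive, among them Rpl39 by 1.86 (adjusted p = 0.00223), Rpl32 by 1.62 (adjusted p = 0.00427) and Rpl5 by 1.58 (adjusted p = 0.0175). The median lay 1.22 above that of all probes (adjusted p = 1.03e-07, and adjusted p = 0.336 with an estimated correlation). One of the 18 was Rps6kb1, a kinase of a ribosomal protein, at 0.67 (adjusted p = 0.450), and at 0.39 without control rat 5. Without this gene 10 of 17 rose (adjusted p = 7.39e-08, and adjusted p = 0.336 with an estimated correlation). Eef1a1, the translation elongation factor that brings aminoacyl-tRNA to the ribosome, rose by 2.69 (SE 0.39, adjusted p = 1.65e-06). Quantile normalisation reduced the median change of the list from 1.44 to 0.55 (adjusted p = 1.11e-06). It ended 7 of the 10 calls, with adjusted p from 0.0509 to 0.307 for Rpl5, and kept those of Rpl32, Rpl39 and Rps7. Centring also ended 7 of the 10 (adjusted p = 0.0566 to 0.107) and kept those of Rpl32, Rpl39 and Rpl5, and by exact permutation 4 of the 10 passed.

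Extracellular matrix and fibroblast markers included 4 of 10 members that rose (5 adjusted over the list alone). S100a4, a calcium-binding protein of fibroblasts, rose by 2.88 (SE 0.40, adjusted p = 5.06e-07), the matrix proteoglycan Bgn by 2.30 (SE 0.39, adjusted p = 3.24e-05) and the related proteoglycan Dcn by 1.40 (adjusted p = 0.0318). Mmp12, a macrophage elastase named after its value was seen, rose by 1.16 (adjusted p = 0.0368). The list was higher by a median of 0.64 relative to all probes (adjusted p = 0.00268, and adjusted p = 0.336 with an estimated correlation). Of the 4 rises only those of S100a4 and Bgn passed after centring and after quantile normalisation. Dcn did not (adjusted p = 0.0782 and 0.180), nor did Mmp12 (adjusted p = 0.0846 and 0.0649).

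Glycolysis and glycogen metabolism was the only tested list called lower. Of its 8 members 1 fell (1 adjusted over the list alone), Pfkfb1 (SE 0.43, adjusted p = 6.76e-04), and the median lay at -0.54 relative to all probes (adjusted p = 0.01003, and adjusted p = 0.336 with an estimated correlation). The enzymes Tpi1 and Pkm differed by -0.75 (adjusted p = 0.334) and -0.59 (adjusted p = 0.456), and after quantile normalisation by -1.34 (adjusted p = 0.0186) and -1.56 (adjusted p = 7.41e-06). Pgam2 and Pgm1, named after their values were seen, differed by 0.15 (adjusted p = 0.924) and -0.10 (adjusted p = 0.933). After quantile normalisation they too passed as lower, at -0.93 (adjusted p = 0.0172) and -0.85 (adjusted p = 0.0230). Pfkfb1 still passed there, and the remaining members did not. The sign of the differences turned between sets of rats, with Tpi1 at -1.89 in rats 1 to 4 and 0.39 in rats 5 to 8. Pkm stood at -1.65 and 0.47, and the list median at -0.64 and 0.43. The median over all probes was -0.03 in rats 1 to 4 and 0.55 in rats 5 to 8. Tpi1, Pkm and the list median lay well below it in rats 1 to 4. In rats 5 to 8 they lay only slightly below it, and camera did not call the list there (adjusted p = 0.492). The median of 0.55 in rats 5 to 8 also includes the low array of control rat 6. Of 4 fast contractile and calcium-handling genes, 1 fell (1 adjusted over the list alone), Mylk2 (SE 0.37, adjusted p = 4.18e-04), while Ckm, the muscle creatine kinase, differed by 0.70 (adjusted p = 0.624) and Tpm1, at the floor on 5 control and 4 denervated arrays, by -0.59 (adjusted p = 0.684). Ckm stood at 1.27 without control rat 1 and 0.43 without control rat 3, and Tpm1 at -0.96 without control rat 6 and -0.38 without denervated rat 6. Mylk2 differed by -2.67 in rats 1 to 4 and by -1.07 in rats 5 to 8. The remaining member, Cacna1s, named after its value was seen, differed by -0.03 (adjusted p = 0.976). After quantile normalisation Cacna1s stood at -0.79 (adjusted p = 0.00230). That list was not called (adjusted p = 0.0526, and adjusted p = 0.366 with an estimated correlation), but passed at the preset correlation after centring (adjusted p = 0.0493) and quantile normalisation (adjusted p = 0.00146).

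In oxidative phosphorylation and the TCA cycle 2 of 8 members rose (2 adjusted over the list alone), Cox8a by 4.84 (SE 0.51, adjusted p = 3.34e-10) and Cox6a1 by 1.36 (adjusted p = 0.0220). Both are subunits of cytochrome c oxidase in the isoform known as the liver type. The list was called higher (adjusted p = 0.0240, and adjusted p = 0.454 with an estimated correlation). Its median lay 0.30 above that of all probes, and Cox8a differed far more than any other member. After quantile normalisation the median change of the list was -0.26 (adjusted p = 0.964). Cox8a was at the floor on 6 of 8 control arrays, and Cox6a1 did not pass after centring (adjusted p = 0.0608), quantile normalisation (adjusted p = 0.0700) or by exact permutation (adjusted p = 0.0609). Ndufa5 differed by 0.69 (adjusted p = 0.347), and by 0.42 without control rat 6. Atp5f1d, named after its value was seen, differed by 0.13 (adjusted p = 0.901). After quantile normalisation it passed as lower, at -0.66 (adjusted p = 0.0375). Of 8 genes of fatty acid uptake and oxidation none passed in limma (0 adjusted over the list alone, 2 at an unadjusted p, 0 by exact permutation), with Hadha at 1.11 (adjusted p = 0.0910), Eci1 at 0.84 and Acat1 at 0.77, or 0.50 without control rat 6 (list adjusted p = 0.288).

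**Figure D3:**
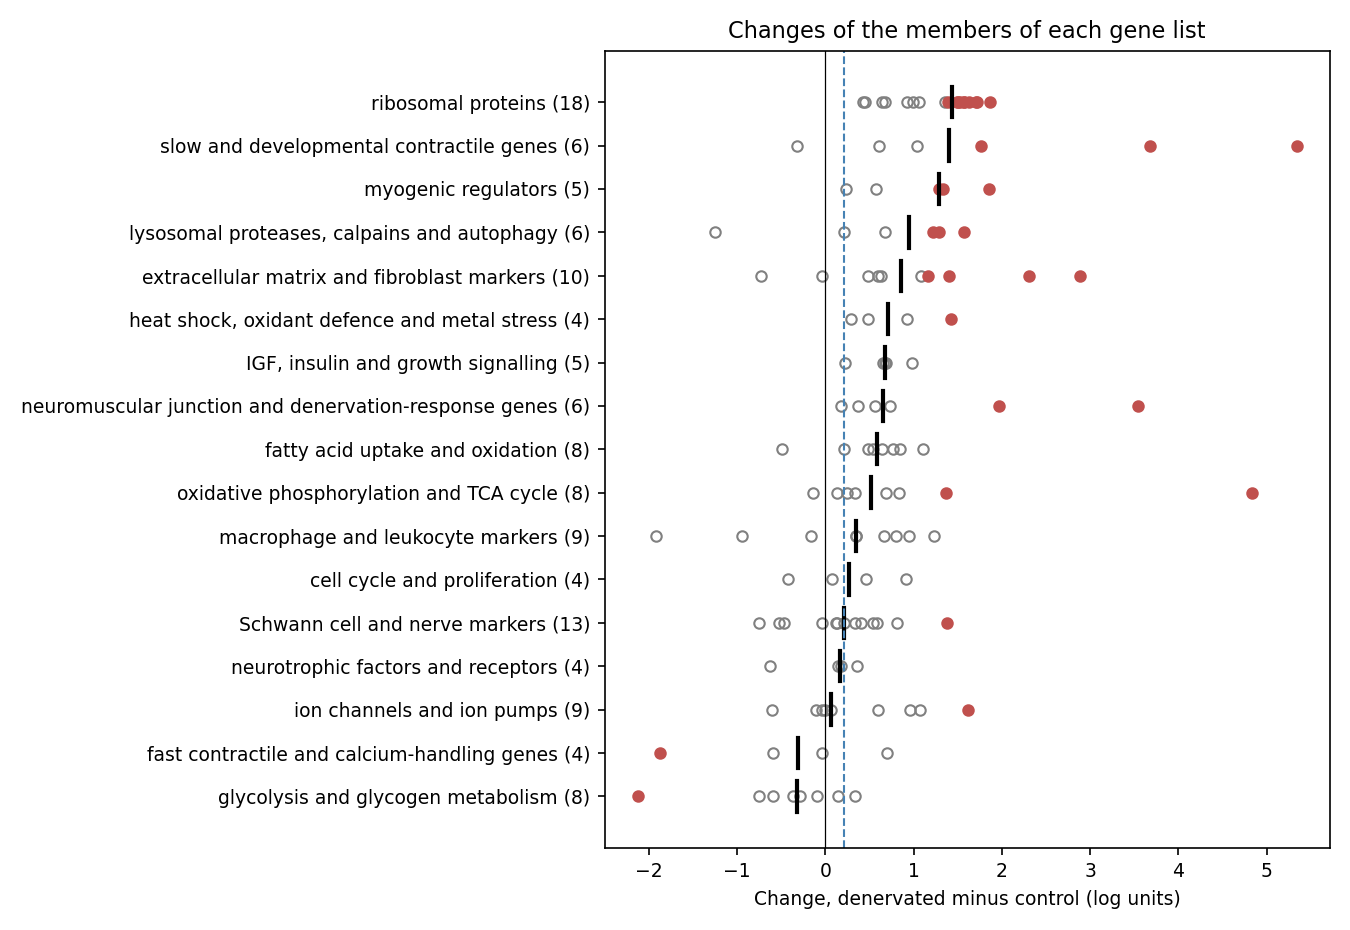
Difference between denervated and control muscle in log units for each measured member of the 17 tested gene lists, with filled red circles for members past the threshold, open grey circles for the others, black bars for list medians and a dashed line at the median of all probes (0.22). Numbers in parentheses are measured members, and ribosomal proteins have all 18 differences above 0.

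Lysosomal proteases, calpains and autophagy genes had 3 of 6 members that rose (3 adjusted over the list alone), the calpain subunits Capns1 by 1.57 (adjusted p = 0.0221) and Capn2 by 1.28 (adjusted p = 0.0450). The third was the lysosomal membrane protein Cd63, by 1.22 (adjusted p = 0.0252). The list was not called (adjusted p = 0.115), and Capns1 and Capn2 did not pass after centring (adjusted p = 0.0684 and 0.0636) or quantile normalisation (adjusted p = 0.182 and 0.0986). Gsta1, a glutathione transferase, rose by 1.42 (adjusted p = 0.00971) as 1 of 4 stress genes (2 adjusted over the list alone; list adjusted p = 0.102), beside Prdx6 at 0.92 and Fth1 at 0.49. Kcnn3, a calcium-activated potassium channel, rose by 1.61 (adjusted p = 0.00348) as 1 of 9 ion channels and pumps (1 adjusted over the list alone; list adjusted p = 0.590), beside Scn8a at 0.96 and Atp7a at 1.07. With a common floor Kcnn3 did not pass (adjusted p = 0.0512). Without control rat 6 Fth1 stood at 0.26 and Atp7a at 0.58.

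Among markers of other cell types, none of 9 macrophage and leukocyte markers passed in limma (2 higher and 1 lower adjusted over the list alone, 3 at an unadjusted p, 1 by exact permutation), and the list was not called (adjusted p = 0.952), with Cxcl1 at -1.92 (adjusted p = 0.0550), Cd48 at 1.24 (adjusted p = 0.0688) and C1qb at 0.95 (adjusted p = 0.138). Cxcl1 was at the floor on 7 of 8 denervated and 4 of 8 control arrays, and with a common floor its adjusted p was 0.469. Of 13 Schwann cell and nerve markers 1 rose (1 adjusted over the list alone; list adjusted p = 0.952), the neurofilament Nefm by 1.38 (adjusted p = 0.0318), which did not pass after centring (adjusted p = 0.126), after quantile normalisation (adjusted p = 0.296) or by exact permutation (adjusted p = 0.125). Nefm differed by 2.61 in rats 1 to 4 and by 0.14 in rats 5 to 8, while Mapt differed by 0.81 and Prx by 0.59. Prx stood at 0.32 without control rat 6 and 0.36 without control rat 8. Scd, a fatty acid desaturase and 1 of 2 measured adipocyte markers, rose by 2.97 (SE 0.50, adjusted p = 3.24e-05) and was at the floor on 5 of 8 control arrays. The other, Acly, which lies outside the naming rule and was named after its value was seen, differed by 0.08 (adjusted p = 0.966). Neither of 2 endothelial and smooth muscle markers passed, and no blood marker was measured.

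None of the 5 genes of IGF, insulin and growth signalling (list adjusted p = 0.288), the 4 cell cycle genes (list adjusted p = 0.952) or the 4 neurotrophic genes (list adjusted p = 0.633) passed in limma, with 0 in each adjusted over the list alone and by exact permutation, and 1, 1 and 0 at an unadjusted p. Grb14 stood at 0.98 and Thra at 0.65, Plk1 at 0.92, Rb1 at 0.46 and Mcm6 at -0.43, and Lifr at -0.62, Socs3 at 0.36 and Nrg1 at 0.18. Without control rat 6 Thra stood at 0.22, Rb1 at 0.01, Socs3 at 0.17 and Nrg1 at 0.01, and without denervated rat 8 Lifr stood at -0.13. Without control rat 1 Socs3 stood at 0.24. Mcm6 stood at -0.20 without control rat 7 and -0.27 without denervated rat 2. Nrg1 ranged from 0.01 to 0.36 without 1 array, the highest without control rat 1; without control rat 5 and denervated rats 2 and 3 it stood at 0.07, 0.09 and 0.29. The proteasome and apoptosis lists had 1 measured member each, and neither passed.

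Further large rises were those of Klk1c2, a kallikrein-type protease, by 3.43 (adjusted p = 1.38e-08), Emb, a transmembrane glycoprotein of the immunoglobulin family, by 2.97 (adjusted p = 4.79e-06), Smc3, a cohesin subunit, by 2.40 (adjusted p = 9.39e-05) and Man2c1, a mannosidase, by 2.39 (adjusted p = 0.00393). Man2c1 was at the floor on 5 of 8 control arrays and did not pass with a common floor (adjusted p = 0.0785). Among the falls, Slc16a3, a lactate transporter, fell by 1.47 (adjusted p = 0.0201), Selenow, a selenoprotein, by 1.48 (adjusted p = 0.0318), Ahsg by 1.34 (adjusted p = 0.0237), Dpysl4 by 1.64 (adjusted p = 0.0368) and Syngr2 by 1.56 (adjusted p = 0.0438). Each of these 5 falls lost its call when some single array was left out. The highest adjusted p was 0.0601 for Slc16a3, 0.0796 for Ahsg, 0.0958 for Dpysl4 and 0.116 for Syngr2, all without denervated rat 2, and 0.136 for Selenow without denervated rat 7. By exact permutation Slc16a3 (adjusted p = 0.0530), Dpysl4 (adjusted p = 0.0976), Syngr2 (adjusted p = 0.101) and Selenow (adjusted p = 0.108) did not pass. The calls of Eif2b4 (-2.30), Cadps and Ppp5c (-2.15) rested on values at the floor, on 7, 8 and 6 of 8 denervated arrays, and with a common floor they had adjusted p-values of 0.303, 0.436 and 0.439. Of the 38 named genes that passed, 16 lost the call without some single array. Rises among them were those of Myod1 (highest adjusted p = 0.140), Nefm (0.121), Capn2 (0.0963), Dcn (0.0865), Cox6a1 (0.0690), Capns1 (0.0601), Cd63 (0.0585) and Myf6 (0.0576).

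The arrays of rats 1 to 4 and of rats 5 to 8 stood apart within both groups, a split found in the data and not given by the labels. The fit to rats 1 to 4 called 18 probes higher and 12 lower, and that to rats 5 to 8 called 131 and 8. With the split as a block in all rats the counts were 117 and 14. The low array of control rat 6 was 1 of the 4 control arrays in rats 5 to 8. The median difference over all probes was -0.03 in rats 1 to 4 and 0.55 in rats 5 to 8. In all rats, leaving out control rat 6 took this median from 0.22 to 0.03. Ribosomal proteins were called in rats 1 to 4 (adjusted p = 0.0122) and rats 5 to 8 (adjusted p = 1.12e-18). So were the slow and developmental contractile (0.00133 and 3.79e-05), junction (0.00954 and 0.0239), myogenic (0.0137 and 0.00663) and matrix lists (0.00385 and 7.50e-04). These p-values are at the preset correlation, and over all rats none of the 5 lists passed with an estimated correlation (adjusted p = 0.0816 to 0.336). The fits used the values as deposited, and no fit by set of rats was run on centred arrays or without control rat 6. How much of the contrast between the sets came from that array was therefore not tested. After quantile normalisation the mean of the ribosomal list differed by 0.19 in rats 1 to 4 (exact permutation p = 0.314). In rats 5 to 8 it differed by 0.96 (exact permutation p = 0.0286). Standard deviations over probes in rats 5 to 8 were 1.19 to 1.58 on control and 1.68 to 1.94 on denervated arrays. In rats 1 to 4 they were 1.26 to 1.82 and 1.46 to 1.94. Oxidative phosphorylation passed in rats 5 to 8 (adjusted p = 1.68e-04) and not in rats 1 to 4 (adjusted p = 0.647). Glycolysis passed in rats 1 to 4 (adjusted p = 6.32e-04) and not in rats 5 to 8 (adjusted p = 0.492). With an estimated correlation over all rats neither passed (adjusted p = 0.454 and adjusted p = 0.336), and the differences between the sets of rats were not tested.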

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

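The tests of the array of control rat 6, of array ranges and of the split between rats 1 to 4 and rats 5 to 8 were chosen only after the results were seen. A sample stood far from the other 7 of its group in 16 of 136 groups of values tested, where chance gives about 6.8, and 10 of the 16 concerned the array of control rat 6.

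More probes were called higher than lower in denervated muscle, 86.5% of the 74 calls. Centring each array, which removes the low position of control rat 6, brought the share to 70.0%, and quantile normalisation, which also gives every array the same range, brought it to 56.5%. Both steps draw the median change to about 0, which itself pulls rises and falls toward balance, and the number of higher calls was 35 after each. These shares, first read as support for an effect of array scale, therefore decide nothing. Without the array of control rat 6 the median difference over all probes went from 0.22 to 0.03, so most of that shift came from this array. The share of higher calls was then 77.4%. The limits for this test and for the number of higher calls were set with the values in view. For the excess of higher calls, array scale and an effect of denervation itself therefore both stay open.

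Ribosomal protein genes were higher, with a median change of 1.44. Among 10000 random lists matched on mean level the highest median was 1.35 and the middle one 0.73, so the list lay at percentile 100. This argues against the brightness of its probes as the whole cause, although bright probes shared part of the change and such lists ignore the correlation between members. A rise in rats 5 to 8 alone stays open, since after quantile normalisation the list mean differed by 0.19 in rats 1 to 4 (exact permutation p = 0.314) and by 0.96 in rats 5 to 8 (exact permutation p = 0.0286, the smallest that 4 against 4 arrays allow). In all rats it differed by 0.57 (exact permutation p = 0.00233), and an effect of denervation remains a hypothesis.

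Arrays of rats 1 to 4 and of rats 5 to 8 stood apart in both groups. Deviations from the group means had a mean correlation across groups of 0.110 within these sets of rats and -0.110 between them, a difference of 0.220. Since the split was found in these arrays, it was compared with the highest of all 35 splits of the rat numbers under each of 40320 renumberings of the denervated arrays (exact permutation p = 0.0143, the smallest this test can give). A batch shared by the groups may account for this, and no biological explanation was tested, since the labels name none.

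Of 100 splits of the 16 arrays, drawn from 6435 possible, only the real one gave as many as 74 changed probes. The highest of the others gave 11. These counts argue against a chance division of the arrays as the source of the 74 calls. By the exact permutation test per probe 67 probes passed at an adjusted p under 0.05. An undrawn split that was run separately exceeded the real one. This was the split of rats 1 to 4 from rats 5 to 8, with 4 arrays of each group on either side. It called 112 probes and points to a structure of the samples. With that split as a block denervation called 131 probes, and within rats 1 to 4 and rats 5 to 8 it called 30 and 139. For the 7 called lists, 1 of 100 splits, again the real one, gave as many and the highest other gave 5, while the split of the rats called 0. These counts are at the preset correlation, and with an estimated correlation 0 of the 7 passed (lowest adjusted p = 0.0816, 2 lists at an unadjusted p).

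The array of control rat 6 had the lowest mean of its group at 6.63 against 8.19 for the next, and the lowest floor at 3.27. Its values of Tnnt2, Myh3 and Tpm1 lay at that floor of 3.27. It was also lowest for Bgn at 5.56, Musk at 6.39, Cd63 at 7.25, Thra at 5.69 and Rb1 at 5.37. Without it Tnnt2 (adjusted p = 1.43e-11), Myh3 (adjusted p = 2.19e-05), Bgn (adjusted p = 1.46e-05) and Cd63 (adjusted p = 0.0243) still passed, while the differences of Musk, Thra, Rb1 and Tpm1, which did not pass with it either, went to 0.45, 0.22, 0.01 and -0.96.

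Selenow was lowest in denervated rat 7 at 5.94 against 9.17 for the next, and without that array its difference was -0.99 (adjusted p = 0.136). Scd was lowest in denervated rat 3 at 7.12, and without it still passed (adjusted p = 2.25e-06). Rpl32 was lowest in the same rat at 9.94, and without it still passed (adjusted p = 0.00142). Musk was lowest in denervated rat 1 at 8.22, Atp7a in denervated rat 2 at 6.21 and Lifr in denervated rat 8 at 4.70, and none of these passed with or without that array. Without denervated rat 8 the difference of Lifr was -0.13.

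Among the 9 reference probes, left out of the main tests and on a scale of their own, 3 were higher in denervated muscle at an unadjusted exact permutation p. The ribosomal protein gene Rps29 stood at 18.5 ± 3.50 against 10.2 ± 4.51 in control muscle (exact permutation p = 0.00202, adjusted over the 9 probes 0.0182). A probe without a gene name stood at 20.5 against 14.7 (exact permutation p = 0.0157, adjusted 0.0706), and Pla2g1b at 4.70 against 3.08 (exact permutation p = 0.0418, adjusted 0.125). Gapdh stood at 8.44 against 12.8 (exact permutation p = 0.126) and Actb at 6.12 against 6.16 (exact permutation p = 0.977).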

How the results depend on the processing

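The common floor, the floor filter, the reference probes, the blocks and fits by sets of rats 1 to 4 and rats 5 to 8, the scalings combined with blocks, and the ribosomal list without Rps6kb1 were chosen only after the data were seen. Of the 38 named genes that passed, 13 kept call and direction in every alternative that tested them (Tnnt2, Cox8a, Myh3, Runx1, Klk1c2, Scd, Emb, S100a4, Eef1a1, Smc3, Bgn, Pfkfb1 and Myog) and 22 kept them when any 1 array was left out; no named gene reversed, and 19 sign changes without a call on either side were counted as no change. The offsets were not run, since the values were already logarithms, and leaving out the filter changed nothing, as it removed no probe. Signal near the floor limits what can be said of dim genes. Where no cause is named, the cause was not tested.

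Against 74 changed, 64 higher and 10 lower probes, the counts were 35 higher after centring, and 35 higher and 27 lower after quantile normalisation. The brighter part of the probes, with fewer tested, gave 5 lower, and array weights 20 lower. The common floor gave 46 changed and 34 higher. Rats 1 to 4 gave 30 changed and 18 higher. Rats 5 to 8, with the low array of control rat 6 among them, gave 139 changed and 131 higher. The set of rats as a block gave 131 changed and 117 higher, with centring 117 changed and 26 lower, and with quantile normalisation 44 lower. Leaving out 1 array gave 43 to 98 changed, 35 to 86 higher and 5 to 14 lower. Counts of changed probes differed by over 1.5 times without control rats 5 (49), 7 (45) and 8 (48) and without denervated rats 1 (43) and 6 (46).

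Rat number as a replicate block gave 113 changed and 17 lower probes, and with centring 141 changed, 108 higher and 33 lower. Numbers were to be taken as pairs only if the deviations of every same-numbered pair correlated by over 0.1. This held for 7 of 8 pairs (highest 0.193) and not for rat 8 (0.059), so the block was kept as an alternative and pairing was not excluded; 5 of 16 arrays correlated best with their own number. With the block and centring the fast contractile list passed at the preset correlation (adjusted p = 0.0445; over all rats without block or centring, adjusted p = 0.366 with an estimated correlation).

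With an estimated correlation 0 of the 7 lists passed in camera, 2 at an unadjusted p. Adjusted p-values were 0.0816 for slow and developmental contractile genes, 0.177 for junction, 0.454 for oxidative phosphorylation and 0.336 for myogenic, glycolysis, matrix and ribosomal lists. The myogenic list did not pass after quantile normalisation (0.0937), in the brighter probes (0.0824) or after quantile normalisation with the set of rats as a block (0.115). Oxidative phosphorylation did not pass after quantile normalisation (0.964), in the brighter probes (0.312), with the common floor (0.0765) or in rats 1 to 4 (0.647), and its direction reversed after quantile normalisation with the block (0.905). The fast contractile list passed after centring (0.0493), quantile normalisation (0.00146), in the brighter probes (0.0247), with array weights (0.0410), in rats 1 to 4 (0.0249), and with the set of rats as a block after centring (0.0403) or quantile normalisation (0.00251); without 1 array it ranged from 0.0251 to 0.168. In rats 5 to 8 glycolysis did not pass (0.492), and fatty acid (0.0463), lysosomal (0.0209) and stress lists (0.0175) did at the preset correlation. Over all rats with an estimated correlation these 3 had adjusted p = 0.663, 0.501 and 0.482, and the fast contractile list 0.366.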

Other observations

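The gene groups tested here were chosen only after changed genes in them were seen, though before the other members were looked at. Besides Scd, 4 further genes of lipid synthesis named after their values were seen were higher in denervated muscle. Pcyt2, of phosphatidylethanolamine synthesis, rose by 2.27 (SE 0.49, adjusted p = 0.00151; at the floor on 4 of 8 control arrays), Acsl4, a fatty acid ligase, by 2.26 (SE 0.56, adjusted p = 0.00736), the desaturase Scd2 by 1.26 (adjusted p = 0.0318) and Dhcr7, of cholesterol synthesis, by 1.22 (adjusted p = 0.0300). Dhcr7 did not pass after centring (adjusted p = 0.0649) or quantile normalisation (adjusted p = 0.171). Without some single array Scd2 and Dhcr7 did not pass (highest adjusted p = 0.0987 and 0.111). Of the cell adhesion genes, Nrcam rose from 8.50 ± 0.49 to 10.46 ± 0.18 (SD, n = 8 per group; adjusted p = 3.24e-05), with all 8 denervated arrays above the highest control, beside the rises of Ncam1 and Emb.

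A wider rise of lipid synthesis was tested as a hypothesis on the 15 other measured genes of the group. Their median change was 0.05 against 0.22 for all probes, 8 of 15 were positive and none passed. For these genes camera gave p = 0.291 in the lower direction (p = 0.505 with an estimated correlation). A median at or below that of all probes had been set beforehand as evidence against the hypothesis, and this was met. That bound was wrong, because taking the called genes out of a group lowers the median of the rest. Several readings of this bound were run after the values were seen, most of which counted against the hypothesis before this was noticed, and it stays open. A wider rise of adhesion genes was tested on 17 other members, again without the called genes, and stays open. Their median change was 0.46, above that of all probes, 12 were positive and none passed (camera p = 0.868, and p = 0.919 with an estimated correlation).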
